A study of Mus musculus with 12 samples.

How the data were processed

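The series holds 12 libraries of ISOS-1 cells in 4 groups of 3: DMSO, SAHA at 1 µM for 24 h, VPA at 2 mM for 36 h and JQ1 at 1 µM for 36 h. Per the labels' protocols, cells grew in DMEM with 10% serum, RNA was extracted with NucleoSpin columns, and libraries were made with QuantSeq 3′ FWD kits. The values are deposited TPM, a length-scaled transcript abundance made by the authors, and the submitters' processing notes name bcl2fastq 2.17, STAR, RSEM, edgeR and the mouse genome mm39 without giving the role of each. The column names carry the gene-level suffix of RSEM. TPM divides by gene length although 3′ tags do not scale with it, so levels of short and long genes are not comparable with each other. TPM sums to the same total in every library and keeps no depth, so the counting precision of each value is unknown. The edgeR tables of the submitters were not among the files held and were not used here.

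The matrix of 55359 gene identifiers and 12 columns was used, with no column left out. It was checked against the 3 sheets that hold each drug beside DMSO. The values equal those of the matrix row by row (332154 per sheet), but in the sheet of DMSO and SAHA the identifiers stand 1 line above their values (55358 of 55359), so this sheet was not used. Of the identifiers, 28119 had no symbol in the matrix. Among 12836 tested genes, 10928 had a symbol of their own in the matrix and 1842 were named from the GENCODE M21 table. That reference is built on GRCm38 rather than the genome of the submitters, so no coordinates are given, and it gave lengths for 12702 of the tested genes (98.96%).

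Genes with at least 1 TPM in at least 3 libraries were kept. Values were taken as log2(TPM + 1), without further scaling, and all 12 libraries were fitted in a model of 4 group means with 8 residual degrees of freedom (R 4.3.3, limma 3.58.1, lmFit and eBayes with an intensity trend and without robust shrinkage). The comparisons were each drug against DMSO and the 3 pairs of drugs. Tests were two-sided, and an adjusted p (Benjamini and Hochberg over all tested genes) under 0.05 counts as a change. Where p-values are described as adjusted over the list alone, the same correction ran over the members of a list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

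A set of 32 gene lists was written before the data were examined. They cover blood and lymphatic endothelial identity, angiogenic ligands and receptors, MYC-linked biosynthesis, S phase, G2/M, CDK inhibitors, p53 targets, markers of response to BET and to HDAC inhibitors, the HDAC family, the BET family with P-TEFb, neuronal and REST-repressed genes, interferon-stimulated genes, antigen presentation, NF-kB and inflammatory genes, AP-1 and immediate early genes, extracellular matrix, mesenchymal and contractile genes, the BCL2 family, cholesterol, glycolysis, the unfolded protein and integrated stress response (called the stress response here), cilia and tubulins, lysosome and autophagy, markers of fibroblasts, leukocytes, pericytes and smooth muscle, and epithelium, and histone, cytosolic ribosomal protein and mitochondrially encoded genes. The 30 lists with at least 2 tested members were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the residuals. The 2 settings differ in more than the correlation. With SAHA, the cholesterol list had an estimated correlation of −0.00337, below the preset, but its unadjusted camera p rose from 0.00561 to 0.0159. A call lost with the estimated setting therefore does not by itself show correlation among the members. Some genes are on more than 1 list, such as Cdkn1a and Hexim1. The lists set no expected direction for their members. The HDAC-inhibitor markers hold Cdkn1a and Mt2 beside Ccnd1 and Tyms, and the BET-inhibitor markers hold Hexim1 beside Myc. Counts of higher and lower members, medians and signed tests of these 2 lists therefore do not measure how far the named response occurred.

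Genes were named by a rule. For each drug against DMSO it took the 10 higher and 10 lower genes with the largest log2 change among those past the threshold, with a mean of at least 5 TPM in either group, no overlap between the 3 and 3 libraries (which chance gives for 10% of genes) and a symbol that is not predicted or clone-based. For pairs of drugs it took 5 and 5. For each list it took up to 4 called members, and Myc, Hexim1, Cdkn1a, Hdac1 to Hdac3, Brd2, Brd3, Pecam1, Cdh5, Kdr and Mki67 in every case. Not every gene so chosen is printed, stable calls were preferred, and some genes the rule chose are not reported here. Spp1 and H2ac24 in JQ1 against DMSO, the genes of the families described further below, and the genes compared between SAHA and VPA other than Cxcl5, H2ac24 and Spp1 fall outside the rule for those comparisons and were chosen after their values were seen.

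The method was tested on simulated data with known changes added to draws from the spread between these libraries. It recovered 27.6, 65.2, 91 and 97% of genes changed 1.5-, 2-, 4- and 8-fold in the SAHA comparison, 29, 63.4, 90.8 and 97.8% in VPA and 29.2, 62.4, 90.6 and 97.6% in JQ1. The changed genes were drawn only from those above 5 TPM in DMSO, so these shares do not cover genes with lower levels. False calls made up 5.84, 5.89 and 4.83% of all calls over 10 draws per comparison, which replaced a first version with fewer draws. Of 10 shifted lists 10 were called, and 0 of 200 unshifted lists. Each shifted list held 25 genes moved by a log2 change of 0.5, and the spread was drawn independently for each gene. These counts therefore do not show how the preset test behaves for correlated genes or smaller shifts. For the overlap of 2 drugs, 100 simulated pairs of unchanged groups were set against the same simulated controls.

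The alternatives fixed before the data were examined were a pseudocount of 0.1 or 5, no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, a fit of the 2 compared groups alone, a replicate block, robust shrinkage, a log2 change of at least 1, leaving out each library, and the estimated camera correlation. Multiplication of TPM by gene length, a restriction to protein-coding nuclear genes, and most settings for the overlaps were added after the data were seen. With a library left out, the model pools the spread of the other groups.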

Results

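Messenger RNA was profiled by sequencing of transcript 3′ ends in ISOS-1, a mouse angiosarcoma cell line that the labels describe as endothelial. The 12 libraries fell into 4 groups of 3 replicates. The vehicle group received DMSO. Vorinostat, given in the labels as SAHA, is a hydroxamate inhibitor of histone deacetylases (HDACs) and was used at 1 µM for 24 h. Valproic acid (VPA), a short-chain fatty acid that also inhibits HDACs, was used at 2 mM for 36 h. JQ1, which displaces BET bromodomain proteins from acetylated chromatin, was used at 1 µM for 36 h. The labels used here give no duration for DMSO, so exposure time cannot be separated from drug in comparisons with DMSO or with SAHA, while VPA and JQ1 were both given for 36 h. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Expression is given as deposited, length-scaled transcript abundance (TPM), mean ± SD of n = 3 libraries. TPM keeps no sequencing depth, and the depth of each library is unknown.

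The 12 libraries listed between 13735 and 14799 genes above 0 TPM, with group means of 14045 ± 324 for DMSO, 14102 ± 403 for SAHA, 14249 ± 286 for VPA and 14508 ± 327 for JQ1. Mitochondrially encoded genes held 11.1 ± 0.0889% of the TPM in DMSO, 11.3 ± 0.339% in SAHA, 12.2 ± 0.245% in VPA and 14.6 ± 0.526% in JQ1. The ribosomal RNA gene Rn18s held 8.98 ± 0.0299%, 9.78 ± 1.22%, 8.51 ± 0.598% and 8.86 ± 0.655% in the same order, with the highest share (11.1%) in SAHA replicate 3. The first principal component carried 31.3% of the variance and placed the JQ1 libraries at 67.2 to 69.4 and the other 9 at −25.3 to −19.4. On the second component (9.92%), DMSO lay at 29.2 to 42.5 and SAHA and VPA at −25.4 to −10.1. Pearson's r across genes, which are not independent replicates, was 0.934 to 0.947 within groups and 0.886 to 0.898 between JQ1 libraries and the others. Between libraries of different groups it reached 0.945, inside the range within groups.

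Most blood endothelial markers were scarce in every group. Of 25 such genes, 8 were listed at 0 in all 12 libraries and 19 stayed below 1 TPM. Cdh5, which encodes VE-cadherin, was listed at 0 in all 12. Pecam1 (CD31) was listed at 0, 0.35 and 0.25 TPM in the DMSO libraries, 0, 0 and 0.26 in SAHA, 0, 0 and 0.34 in VPA, and 0.52, 0.36 and 1.01 in JQ1. Kdr, the receptor VEGFR2, had 0.11, 0.12 and 0.27 TPM in DMSO, 0.81, 0.72 and 0.29 in SAHA, 0.25, 0.97 and 0.65 in VPA, and 0.09, 0 and 0.37 in JQ1. Cd34, expressed by endothelial and progenitor cells, reached 103 ± 8.41 TPM in DMSO, and podoplanin (Pdpn), a lymphatic endothelial marker, 73.3 ± 4.24. Among markers of other cells, 5 of 10 fibroblast genes, 4 of 11 leukocyte genes, 2 of 9 epithelial genes and 1 of 9 pericyte or smooth muscle genes reached 1 TPM in some library, against 6 blood endothelial and 2 of 10 lymphatic genes. The surface glycoprotein Thy1, listed with the fibroblast markers, stood at 154 ± 7.2 TPM in DMSO.

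The SAHA libraries address how inhibition of HDACs changed transcription in these cells. Vip (ENSMUSG00000019772), which encodes a neuropeptide, rose 15.6-fold from 4.06 ± 1.79 TPM in DMSO to 63.2 ± 1.41 in SAHA (log2 change 3.74, SE 0.275, adjusted p = 3.14e-05). Gchfr, the feedback regulator of GTP cyclohydrolase, rose from 23.5 ± 3.01 to 114 ± 10.6 TPM (log2 change 2.24, adjusted p = 0.00111), and Gap43, a growth-associated protein of neurons, from 25.9 ± 3.46 to 105 ± 3.39 (1.99, adjusted p = 0.00111). Thy1 rose 3.67-fold to 567 ± 81.5 TPM (1.86, adjusted p = 4.25e-06), and Mt2, a metallothionein, rose from 1308 ± 62.9 to 2846 ± 99.7 (1.12, adjusted p = 3.63e-07). Among genes that fell, the proteoglycan gene Aspn went from 13.9 ± 1.48 to 4.21 ± 1.65 TPM (−1.56, adjusted p = 0.0066) and the snoRNA host gene Snhg12 from 71.2 ± 7.49 to 25.4 ± 6.75 (−1.48, adjusted p = 0.00401).

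Other large rises with SAHA were those of Upp1, uridine phosphorylase (6.05 ± 2.05 against 0.56 ± 0.604 TPM, adjusted p = 0.00514), and the centrin gene Cetn4 (17.7 ± 5.71 against 3.13 ± 0.841, adjusted p = 0.00111). The alpha-globin gene Hba-a2 was listed at 15.7 ± 1.08 against 0.92 ± 0.807 TPM (adjusted p = 0.0013), a value that is uncertain because its near-identical copy can share reads. Pik3r1, a regulatory subunit of PI3-kinase, fell from 16.2 ± 1.83 to 5.7 ± 2.13 TPM (adjusted p = 0.00641), a call that ended in a fit of these 2 groups alone. Of the 20 genes named for the size of their change, 11 kept their call whichever library was left out. The other 9 lost it without at least 1 library.

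Of 15 tested HDAC-inhibitor response markers, 8 rose and none fell with SAHA (10 and none adjusted over the list alone; camera adjusted p = 8.84e-10, and 0.00304 with an estimated correlation). They included Mt2, Txnip and Cdkn1a, the gene of the cyclin-dependent kinase inhibitor p21, which rose from 23.5 ± 2.49 to 52.7 ± 6.3 TPM (log2 change 1.13, adjusted p = 0.00146). The call of Txnip (19.6 ± 3.21 against 4.25 ± 3.3 TPM, adjusted p = 0.0237) ended without SAHA replicate 1 (0.076), 2 (0.0707) or 3 (0.0531). The marker list sets no direction for its members, so its counts do not say how many responded in a known way. Of 6 CDK inhibitors, 2 rose (2 adjusted over the list alone; adjusted p = 0.00289, and 0.0413 estimated): Cdkn1a and Cdkn2a, which went from 796 ± 7.82 to 1053 ± 11.2 TPM. Of 13 NF-kB and inflammatory genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 2.77e-05, and 0.0279 estimated). The chemokine genes Ccl2 (53.3 ± 7.01 to 127 ± 8.87 TPM) and Ccl7 (13.5 ± 4.71 to 46.7 ± 4.92) rose, and Nfkbia, the NF-kB inhibitor, fell from 106 ± 5.53 to 71.9 ± 6.65.

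Of 30 genes of MYC-linked biosynthesis, 5 fell and 1 rose with SAHA (7 and 1 adjusted over the list alone; adjusted p = 0.000308, and 0.0263 estimated). The nucleolar protein gene Npm1 fell from 2667 ± 76.4 to 1716 ± 82.1 TPM (log2 change −0.64, adjusted p = 3.14e-05), and the transferrin receptor gene Tfrc from 64.5 ± 3.06 to 34.2 ± 2.45 (−0.90, adjusted p = 0.000261). The list of 25 G2/M and mitosis genes had a median of −0.20 (adjusted p = 0.000143, and 0.0279 estimated), with 1 member past the threshold over all genes and 5 lower adjusted over the list alone. That member was the kinase gene Plk1 (48 ± 6.72 against 67.5 ± 2.19 TPM, adjusted p = 0.0435). Its call ended without any DMSO or JQ1 replicate, SAHA replicate 1 or 2, or VPA replicate 1, with the highest adjusted p (0.133) without SAHA replicate 2. The proliferation marker Mki67 stood at 14.8 ± 1.17 against 20.1 ± 1.12 TPM (adjusted p = 0.0614).

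Of 5 tested fibroblast markers, 3 rose with SAHA (4 adjusted over the list alone; adjusted p = 0.00125, and 0.0413 estimated): Thy1, Mfap5 and Dcn. The call of Dcn (3.15 ± 1.52 against 0.143 ± 0.248 TPM) ended without DMSO replicate 1 or 3 or SAHA replicate 1 or 3 (adjusted p up to 0.0971, without SAHA replicate 3). That of Mfap5 (21.5 ± 7.96 against 5.8 ± 1.27) ended without any DMSO replicate or SAHA replicate 1 or 2 (up to 0.0923, without SAHA replicate 1). The epithelial marker Krt19, the 1 tested member of its list, rose from 11.3 ± 0.641 to 23.8 ± 1.67 TPM (1 adjusted over the list alone; adjusted p = 0.00443). Cd34 (to 194 ± 9.85 TPM, adjusted p = 0.000589) and Pdpn (to 115 ± 7.61, adjusted p = 0.000918) rose as the called members of 5 blood endothelial and 2 lymphatic genes. Adjusted over the list alone, these lists had 1 higher, and 1 higher and 1 lower, member. The blood endothelial median (−0.05) differed in sign from its mean (0.01) and test (adjusted p = 0.594), and the lymphatic list had adjusted p = 0.412.

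Another 6 lists passed with the preset correlation but not with an estimated one. Of 85 cytosolic ribosomal protein genes, 21 fell and 3 rose (36 and 5 adjusted over the list alone; adjusted p = 1.37e-09), among them Rps29 from 6723 ± 150 to 5264 ± 159 TPM. The adjusted p was 0.124 with an estimated correlation, and quantile normalization gave 12 lower members and multiplication by gene length 11. Of 22 lysosome and autophagy genes, 3 rose (3 adjusted over the list alone; adjusted p = 0.00371), including cathepsin L (Ctsl, 131 ± 6.82 to 241 ± 3.7 TPM). For them the adjusted p was 0.0549 with an estimated correlation, the same value as for 6 neuronal and REST-repressed genes (1 rose, 2 adjusted over the list alone; adjusted p = 0.00371 preset) and for 22 cholesterol genes. Of the last, 2 fell (2 adjusted over the list alone; adjusted p = 0.0153, and 0.0644 without SAHA replicate 2), including Cyp51 from 206 ± 7.55 to 159 ± 10.5 TPM. Of 12 cilia and tubulin genes, 3 rose (3 adjusted over the list alone; adjusted p = 0.0138, and 0.0701 without SAHA replicate 1), including Tubb2b from 32.8 ± 4.08 to 70.4 ± 3 TPM. Their adjusted p was 0.0601 with an estimated correlation. Of 8 antigen presentation genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0374, and adjusted p = 0.141 with an estimated correlation). Both class I genes rose, H2-D1 from 12.6 ± 3.4 to 36.8 ± 2.86 TPM and H2-K1 from 53 ± 12.7 to 114 ± 3.37, with levels that are uncertain because such paralogs can share reads. The antigen presentation call ended without DMSO replicate 1 (0.0752), SAHA replicate 1 (0.0668) or 2 (0.0632), or JQ1 replicate 1 (0.0582), 2 (0.0596) or 3 (0.059), with a filter at 5 TPM (0.0651), in a fit of the 2 groups alone (0.112), after multiplication by gene length (0.0529) and for protein-coding nuclear genes alone (0.051).

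The remaining lists did not pass with SAHA under the reported settings. Of 19 mesenchymal and contractile genes, 5 rose and 2 fell (7 and 4 adjusted over the list alone; adjusted p = 0.0886), with S100a4 down from 6719 ± 79.3 to 5563 ± 189 TPM. Of 21 AP-1 and immediate early genes, 3 rose (5 higher and 1 lower adjusted over the list alone), including Junb from 28 ± 2.07 to 53 ± 5.12 TPM, and of 25 extracellular matrix genes, 3 rose (4 and 3), including fibronectin (Fn1) from 51.4 ± 7.64 to 87.4 ± 7.69. Of 9 angiogenic genes, 2 rose (4 adjusted over the list alone), and these last 3 lists had the same adjusted p of 0.0886. The counts were 3 higher and 1 lower of 20 stress response genes (4 and 2 adjusted over the list alone; 0.23), 2 higher of 15 glycolysis genes (2; 0.0816), 1 higher of 16 p53 targets (1; 0.23) and 3 higher of 15 mitochondrially encoded genes (4; 0.128). There was 1 lower member among 25 S-phase genes (1 adjusted over the list alone; 0.0872), 13 interferon-stimulated genes (1; 0.41), 49 histone genes (0; 0.23) and 10 genes of the BET family and P-TEFb (2, with 1 higher; 0.0596). Without SAHA replicate 3 the glycolysis (0.0492), mitochondrial (0.0277) and BET family (0.0277) lists passed, and the last did so without DMSO replicate 3 (0.0406). Without a filter, 17 rather than 12 lists passed: S phase (0.0374), AP-1 (0.0376), matrix (0.0374), glycolysis (0.0235) and the BET family (0.0235) were added, and AP-1 also passed with a filter at 5 TPM (0.0442). The lower BET family gene was Brd2, which fell from 645 ± 13.7 to 475 ± 15.3 TPM (adjusted p = 0.000684), while Brd3 (29.9 ± 2.06 against 33.9 ± 2.62, adjusted p = 0.555) did not pass.

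For the lists without a called gene, limma gave 0 calls with SAHA among 10 HDAC family genes (1 at an unadjusted p under 0.05; camera adjusted p = 0.876), 12 BCL2 family genes (1; 0.876), 7 BET-inhibitor response markers (2; 0.836), 3 leukocyte markers (0; 0.876) and 1 pericyte marker (0). Adjusted over the list alone, 1 BET-inhibitor response marker was higher and no member of the other 4 lists passed. Median, mean and test differed in sign for the HDAC family (−0.04, 0.06, up), the BET-inhibitor markers (0.02, −0.02, up), the leukocyte markers (−0.13, 0.10, up) and the mitochondrially encoded genes (0.05, −0.12, up). Hdac1 stood at 74.6 ± 5.91 against 65.4 ± 2.82 TPM (adjusted p = 0.299), Hdac2 at 92.5 ± 8.79 against 82.7 ± 17.5 (0.56) and Hdac3 at 5.2 ± 0.631 against 6.62 ± 1.24 (0.389). Myc had 23.7 ± 1.39 against 21.5 ± 1.22 TPM (0.649) and Hexim1, an inhibitor of the elongation factor P-TEFb, 8.45 ± 1.59 against 11.4 ± 1.98 (0.211).

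Of 12836 genes tested, 396 were higher and 270 lower with SAHA, 5.19% in all, and 133 and 54 of these changed at least 2-fold. Both counts moved by over 1.5 times without any of 6 libraries: 231 higher and 134 lower without DMSO replicate 1, 251 and 126 without DMSO replicate 2, 240 and 138 without DMSO replicate 3, 238 and 163 without SAHA replicate 1, 218 and 147 without SAHA replicate 2, and 243 and 149 without SAHA replicate 3. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low TPM.

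**Figure D1:**
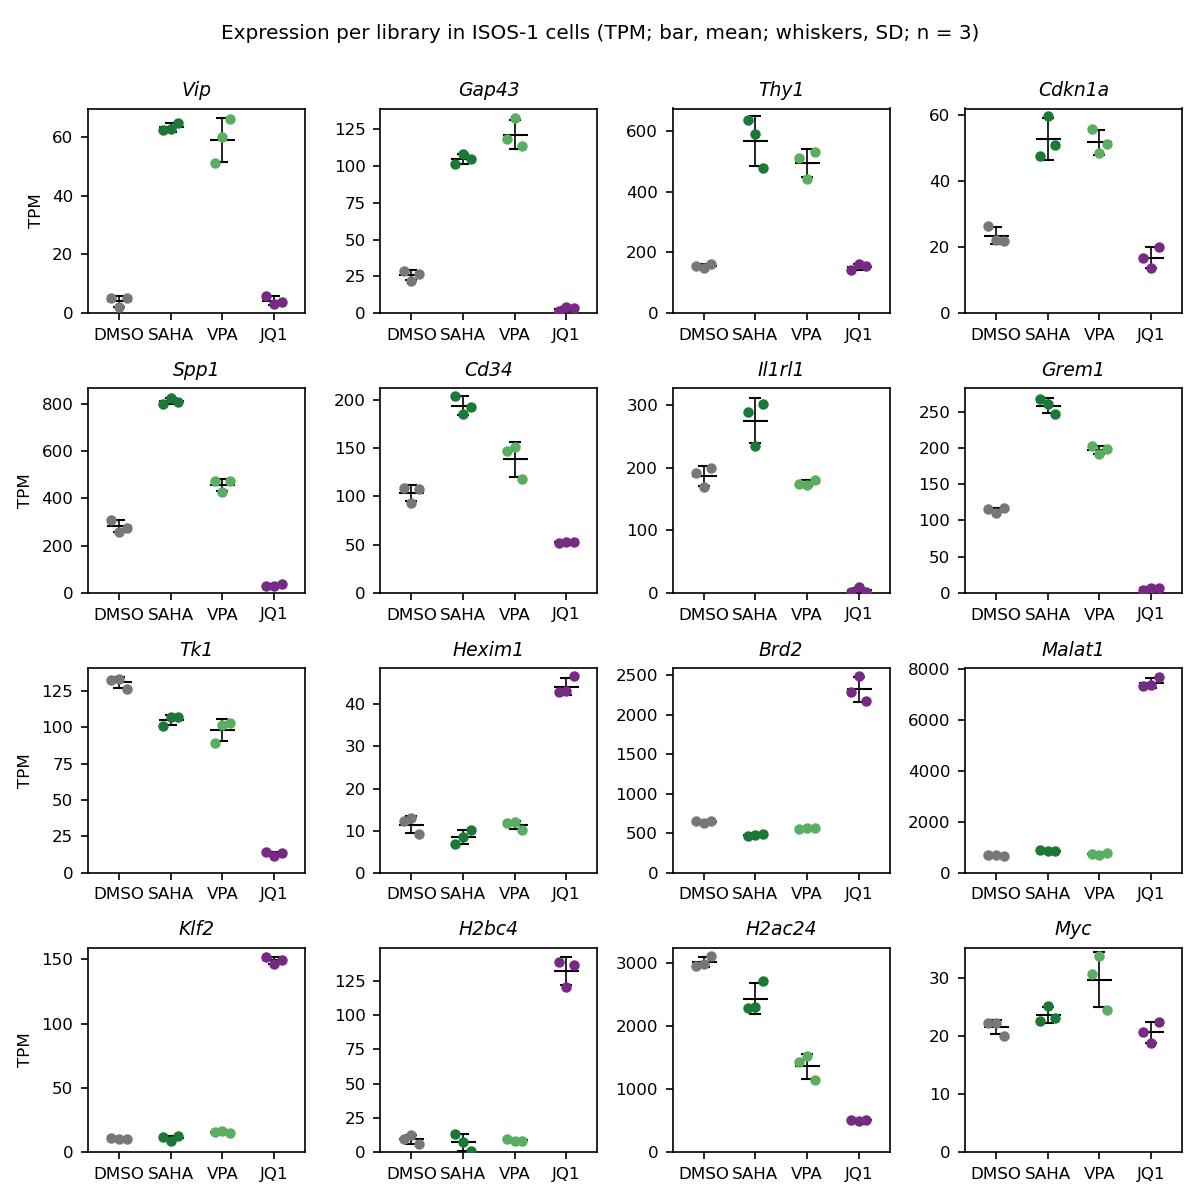
Expression of 16 genes in TPM (vertical axes, from 0) in the 4 groups; each point is 1 library, bars are group means and whiskers the SD of 3 libraries. Vip lies near 60 TPM in SAHA and VPA and near 4 in DMSO, whereas Malat1 reaches 7479 TPM in JQ1 against 694 in DMSO.

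VPA, the other HDAC inhibitor, gave a similar set of leading genes. Vip rose from 4.06 ± 1.79 TPM in DMSO to 58.9 ± 7.49 (14.5-fold, log2 change 3.63, SE 0.275, adjusted p = 7.45e-05). Gap43 rose to 122 ± 9.96 TPM (2.19, adjusted p = 0.000718) and Thy1 to 494 ± 45.8 (1.67, adjusted p = 2.04e-05). Add3, which encodes the cytoskeletal protein gamma-adducin, rose from 3.46 ± 0.818 to 17.5 ± 3.86 TPM (2.05, adjusted p = 0.000421). Aspn fell to 2.84 ± 0.502 TPM (−1.96, adjusted p = 0.00266), and Rdh10, a retinol dehydrogenase, fell from 12.2 ± 1.18 to 4.27 ± 0.834 (−1.33, adjusted p = 0.00868). Of the 20 genes named for size, 10 kept their call whichever library was left out. The other 10 lost it without at least 1 library.

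Of 15 HDAC-inhibitor response markers, 9 rose and none fell with VPA (10 and none adjusted over the list alone; camera adjusted p = 2.18e-09, and 0.0021 estimated), and 6 rose with median-of-ratios scaling or quantile normalization. Cdkn1a rose to 51.8 ± 3.78 TPM (log2 change 1.11, adjusted p = 0.00257). Of 30 MYC-linked genes, 6 fell (13 adjusted over the list alone; adjusted p = 5.96e-12, and 0.00105 estimated): Npm1 to 1678 ± 60 TPM (adjusted p = 3.88e-05), Dkc1, a component of box H/ACA snoRNPs, from 565 ± 6.28 to 381 ± 41.8, nucleolin (Ncl) from 982 ± 17.6 to 743 ± 20, and 3 more. Of 6 neuronal and REST-repressed genes, 2 rose (5 adjusted over the list alone; adjusted p = 0.000121, and 0.0283 estimated): Gap43 and the tubulin gene Tubb3, from 9.29 ± 1.09 to 19.3 ± 3.38 TPM. The Tubb3 call ended without DMSO replicate 1 or 3 or VPA replicate 2 or 3, with an adjusted p of up to 0.0599 without VPA replicate 2. Of 5 fibroblast markers, Thy1 rose (4 higher adjusted over the list alone; adjusted p = 0.00033, and 0.0293 estimated).

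Of 49 replication-dependent histone genes, 5 fell with VPA (6 adjusted over the list alone; adjusted p = 0.000451, and 0.0265 estimated), though near-identical copies make single histone levels uncertain. In every comparison, how much of this histone RNA the 3′-end libraries capture is not known either. H2ac24 fell from 3014 ± 80 to 1363 ± 200 TPM (log2 change −1.16, adjusted p = 0.000109) and the linker histone gene H1f5 from 67.4 ± 8.17 to 25.8 ± 6.89 (−1.38, adjusted p = 0.005). Of 85 cytosolic ribosomal protein genes, 13 fell (31 adjusted over the list alone; adjusted p = 5.74e-16), including Rplp0 from 992 ± 15.9 to 772 ± 12.6 TPM. That list had adjusted p = 0.0556 with an estimated correlation, and 28 lower members with median-of-ratios scaling but 3 higher and 7 lower with quantile normalization. Of 15 mitochondrially encoded genes, 8 rose (9 adjusted over the list alone; adjusted p = 6.36e-06), including COX1 from 1244 ± 27 to 1512 ± 60.9 TPM. Their adjusted p was 0.107 with an estimated correlation, with 7 higher and 1 lower members after median-of-ratios scaling and 5 and 2 after quantile normalization.

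Several other lists passed with VPA with the preset correlation but not with an estimated one. Of 22 lysosome genes, 4 rose (4 adjusted over the list alone; adjusted p = 0.0039), among them Ctsl to 187 ± 7.83 TPM, against 2 with median-of-ratios scaling and 1 with quantile normalization. Of 12 cilia and tubulin genes, 2 rose (3; 0.0095), including Tubb2b to 86.2 ± 10.5 TPM, and of 22 cholesterol genes, Cyp51 fell to 154 ± 7.7 (1; 0.0104). For each of these 3 lists the adjusted p was 0.0556 with an estimated correlation. Of 8 antigen presentation genes, H2-D1 and H2-K1 rose, to 36.6 ± 3.1 and 103 ± 18.7 TPM (5 higher and 1 lower adjusted over the list alone; 0.0095), and the list had adjusted p = 0.107 with an estimated correlation and 0.0703 in a fit of the 2 groups alone. Of 13 NF-kB and inflammatory genes, 3 rose (6 adjusted over the list alone; 0.0205), including Ccl2 to 88.3 ± 13.3 TPM. That call ended without DMSO replicate 3 (0.0592) or VPA replicate 1 (0.0955) and with a filter at 5 TPM (0.0848), and the list had adjusted p = 0.11 with an estimated correlation. For 25 G2/M genes limma called 0 members, 1 at an unadjusted p under 0.05 and none adjusted over the list alone. Their list passed at 0.0452 with a median of −0.11, and had adjusted p = 0.135 with an estimated correlation. It did not pass without DMSO replicate 1 (0.0785) or 3 (0.122) or VPA replicate 1 (0.0955) or 3 (0.127). Nor did it pass with a replicate block (0.0604), with a filter at 5 TPM (0.0739) or after multiplication by gene length (0.0586). Mki67 stood at 21.6 ± 0.943 TPM (adjusted p = 0.694).

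The remaining lists did not pass with VPA under the reported settings. Of 19 mesenchymal and contractile genes, 2 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.383). Tpm2, a tropomyosin, rose from 54.3 ± 5.19 to 110 ± 3.16 TPM, and S100a4 fell from 6719 ± 79.3 to 4874 ± 205. Of 9 angiogenic genes, 2 rose (3; 0.0866), including the Notch ligand Jag1 from 0.887 ± 0.28 to 5.39 ± 0.51 TPM, and of 6 CDK inhibitors, 2 rose (3 higher and 1 lower adjusted over the list alone; 0.107, and 0.0459 with quantile normalization). Of 21 AP-1 genes, 4 rose (5 higher and 1 lower; 0.165), including Ier3 from 225 ± 24.8 to 346 ± 11.6 TPM, and 1 did with median-of-ratios scaling. Of 25 matrix genes, Col1a2 fell from 470 ± 19.6 to 374 ± 10.6 TPM (4 higher and 4 lower; 0.482), and 3 fell with median-of-ratios scaling. There was 1 lower gene of 25 in S phase (2; 0.272) and 1 of 10 in the BET family (1; 0.304), 1 higher of 15 in glycolysis (1; 0.868), and 2 higher of 20 in the stress response list (2 higher and 1 lower; 0.75). Krt19 rose to 31 ± 6 TPM (1 adjusted over the list alone; adjusted p = 0.00104) and Pdpn to 106 ± 0.953 (0.00422), in a lymphatic list of 2 (1; 0.454). Of 5 blood endothelial genes 1 rose (1; 0.489): Cd34, at 139 ± 18.2 TPM (adjusted p = 0.0424), whose call ended without any of the 12 libraries but VPA replicate 3, with a highest value of 0.137 without DMSO replicate 2. The lower BET family gene was Brd2 (561 ± 3.99 TPM, adjusted p = 0.0474), whose call ended without any library but JQ1 replicates 2 and 3, with a highest value of 0.134 without DMSO replicate 3.

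With VPA, limma made 0 calls among 16 p53 targets (3 at an unadjusted p under 0.05; camera adjusted p = 0.666), 7 BET-inhibitor response markers (2; 0.454), 10 HDAC family genes (2; 0.86), 13 interferon-stimulated genes (3; 0.107), 12 BCL2 family genes (1; 0.0866, and 0.0459 with quantile normalization), 3 leukocyte markers (1; 0.868) and 1 pericyte marker (0). Adjusted over the list alone, 1 BET-inhibitor marker was higher and none in the other 6 lists. The small positive medians of the p53 targets (0.07), BET-inhibitor markers (0.11) and HDAC family (0.05) turned negative with quantile normalization (−0.02, −0.02 and −0.01), and those of glycolysis (0.01) and the stress response (0.03) with median-of-ratios scaling (−0.045 and −0.032). Median, mean and test differed in sign for the BET family (−0.10, 0.01, down), the matrix genes (−0.03, 0.05, down), glycolysis (0.01, 0.07, down) and the leukocyte markers (−0.26, 0.11, down). Values that did not pass were Myc at 29.7 ± 4.72 TPM (adjusted p = 0.0959), Hexim1 at 11.3 ± 0.969 (1), Hdac1 at 77 ± 6.57 (0.21), Hdac2 at 80.8 ± 7.73 (0.983), Hdac3 at 7.18 ± 0.354 (0.778) and Brd3 at 31.5 ± 0.0964 (0.769).

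With VPA, 379 genes were higher and 169 lower, 4.27% of those tested, and 141 and 35 changed at least 2-fold. Lower genes were 30.8% of the calls, and 48.5% with median-of-ratios scaling, which gave 264 lower genes. Both counts moved by over 1.5 times without any of 6 libraries: 221 higher and 73 lower without DMSO replicate 1, 232 and 85 without DMSO replicate 2, 231 and 76 without DMSO replicate 3, 209 and 98 without VPA replicate 1, 210 and 96 without VPA replicate 2, and 213 and 102 without VPA replicate 3.

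Compared directly, few genes passed the threshold between SAHA and VPA, which were given at different doses and times. Cxcl5, a neutrophil chemokine, stood at 61.9 ± 6.35 TPM with SAHA and 27.4 ± 1.14 with VPA (log2 difference 1.14, 95% interval 0.87 to 1.42, adjusted p = 0.00258). H2ac24 stood at 2431 ± 241 and 1363 ± 200 TPM (0.84, 0.63 to 1.05, adjusted p = 0.00317), a call that ended in a fit of these 2 groups alone. Cdkn2a was higher with SAHA (1053 against 742 TPM, 0.50, 0.42 to 0.59, adjusted p = 0.000297), as were Junb (53 against 32.7, 0.67, 0.46 to 0.88, adjusted p = 0.0154) and Mt2 (2846 against 2403, 0.24, 0.15 to 0.34, adjusted p = 0.0365). Tfrc was lower with SAHA (34.2 against 50 TPM, −0.54, −0.73 to −0.35, adjusted p = 0.0235). These last 4 calls were not repeated with libraries left out. Osteopontin (Spp1) stood at 811 ± 13.1 and 457 ± 26.4 TPM (0.83, 0.58 to 1.08, adjusted p = 0.0132), and its call ended without SAHA replicate 2 or 3 (0.0668 without the latter).

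For other leading genes the difference did not pass, and its interval shows what the data allow. The log2 difference of SAHA from VPA was 0.11 for Vip (−0.50 to 0.71, adjusted p = 0.928), −0.21 for Gap43 (−0.74 to 0.33, 0.805), 0.02 for Cdkn1a (−0.31 to 0.34, 0.984) and 0.03 for Npm1 (−0.07 to 0.13, 0.845). It was 0.49 for Cd34 (0.27 to 0.71, 0.0668), 1.02 for Gchfr (0.41 to 1.62, 0.173) and 1.08 for H1f5 (0.62 to 1.54, 0.0551), whose intervals exclude 0 before adjustment over all genes. In all, 34 genes were higher with SAHA and 24 with VPA, 58 together, with 1464 of 12836 at an unadjusted p under 0.05. The 58 became 38 without SAHA replicate 1, 18 without SAHA replicate 2, 15 without SAHA replicate 3, 21 without VPA replicate 1, 32 without VPA replicate 2 and 21 without VPA replicate 3, and 88 with median-of-ratios scaling.

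Of the 914 genes called with SAHA or VPA, 51 (5.58%) differed in the direct comparison. The others are not shown to respond equally, since the simulation recovered only 27.6% of 1.5-fold changes for SAHA against DMSO. The calls shared 208 higher and 92 lower genes, and none in opposite directions, where independent lists of these sizes would share 11.7 and 3.55. Simulated unchanged groups set against the same controls shared 0, but an adjusted threshold is built to leave few calls in groups with no effect, so this 0 does not bound what the shared controls add. The correlation of log2 changes across genes was 0.586 (simulated 0.499) and their covariance 0.168 (simulated 0.0826), a difference of 0.0852. The 3 DMSO libraries are too few to split, so part of the excess may come from the shared controls. The numbers for independent lists also treat genes of every expression level as equally likely to be called, so they are no firm baseline. The 300 shared calls became 171, 181 and 163 without DMSO replicates 1, 2 and 3, 197 and 190 without SAHA replicates 1 and 2, and 197 and 181 without VPA replicates 1 and 2.

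**Figure D2:**
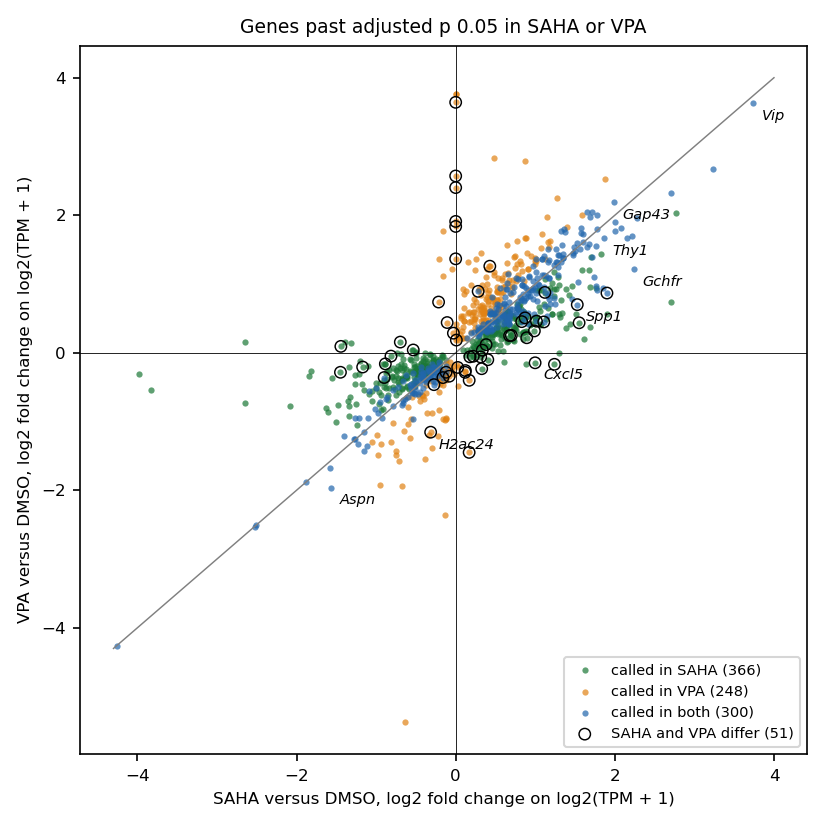
Log2 change against DMSO with SAHA (horizontal) and VPA (vertical), 1 point per gene called with SAHA, VPA or both (300 genes in both); circles mark the 51 genes that differed directly and the line marks equality. Circles surround few of the 914 points, and both axes share the same DMSO libraries.

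JQ1, the BET inhibitor, changed far more genes. Klf2 (ENSMUSG00000055148), a transcription factor of endothelial cells, rose 14.2-fold from 10.5 ± 0.441 TPM in DMSO to 149 ± 2.64 (log2 change 3.71, SE 0.123, adjusted p = 3.17e-09). The nuclear long non-coding RNA Malat1 (ENSMUSG00000092341) rose from 694 ± 32 to 7479 ± 193 TPM (3.43, SE 0.0496, adjusted p = 8.19e-12). Il1rl1 (ENSMUSG00000026069), the receptor of interleukin-33, fell from 187 ± 15.5 to 3.88 ± 4.25 TPM (−5.61, SE 0.429, adjusted p = 2.39e-06). Crabp1, which binds retinoic acid, fell from 131 ± 3.25 to 5.61 ± 1.71 TPM (−4.36, adjusted p = 9.53e-09), and the BMP antagonist Grem1 from 114 ± 3.01 to 6.23 ± 1.41 (−4.01, adjusted p = 2.33e-09).

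Further rises were those of Id2, an inhibitor of basic helix-loop-helix factors (10.8 ± 2.88 to 106 ± 11.9 TPM), Txnip (4.25 ± 3.3 to 44.9 ± 8.34) and Chac1, a glutathione-degrading enzyme (4.1 ± 2.26 to 38.2 ± 5.25). The histone genes H2bc4 (9.55 ± 3.27 to 132 ± 10.1 TPM) and H4c9 (11.5 ± 3.61 to 114 ± 2.89) rose as well, with levels that are uncertain where copies share reads. Further falls were those of Cxcl5 (30.5 ± 2.9 to 0.753 ± 0.124 TPM), the cGMP-dependent kinase gene Prkg2 (221 ± 14 to 13.2 ± 3.26), the immunoproteasome subunit gene Psmb10 (113 ± 13.1 to 6.66 ± 2.14), the Wnt regulator gene Dkk2 (80.8 ± 0.827 to 5.75 ± 1.25) and Hmga2, an architectural chromatin protein (141 ± 2.31 to 11.5 ± 1.97). The 20 genes named for size all kept their call whichever library was left out. Spp1 fell from 281 ± 25.2 to 32.7 ± 6.17 TPM (log2 change −3.08).

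Proliferation genes fell together with JQ1. Of 25 S-phase and replication genes, 24 fell (24 adjusted over the list alone; camera adjusted p = 5.46e-14, and 0.000353 estimated), among them thymidine kinase (Tk1) from 131 ± 3.75 to 13 ± 1.3 TPM (log2 change −3.24, adjusted p = 1.21e-09) and Mcm3 of the replicative helicase from 84.3 ± 3.59 to 15.2 ± 3.1. Of 25 G2/M and mitosis genes, 24 fell (24 adjusted over the list alone; adjusted p = 5.66e-16, and 0.000448 estimated), including Plk1 to 12.4 ± 0.648 TPM, Ube2c from 263 ± 13.6 to 51.6 ± 3.86, and Mki67 from 20.1 ± 1.12 to 7.18 ± 0.1 (−1.36, adjusted p = 4.62e-06). Of 30 MYC-linked genes, 26 fell and 1 rose (29 and 1 adjusted over the list alone; adjusted p = 1.55e-16, and 0.000288 estimated). Dkc1 fell from 565 ± 6.28 to 105 ± 6.25 TPM (−2.42, adjusted p = 2.56e-09), and Mat2a, a methionine adenosyltransferase, rose from 74.3 ± 9.81 to 118 ± 10.4. Myc itself stood at 20.6 ± 1.79 TPM against 21.5 ± 1.22 (−0.06, adjusted p = 0.779). Of 6 CDK inhibitors, 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.593), with Cdkn2b rising from 20.4 ± 2.51 to 42 ± 4.01 TPM and Cdkn1b from 22.9 ± 3.74 to 42.3 ± 3.33. Cdkn1a, at 16.8 ± 3.25 TPM (−0.47, adjusted p = 0.0293), lost its call without DMSO replicate 1, JQ1 replicate 1 or JQ1 replicate 2 (up to 0.106, without the last) and with quantile normalization (0.087).

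Of 22 lysosome and autophagy genes, 17 rose and none fell with JQ1 (18 and none adjusted over the list alone; adjusted p = 2.04e-13, and 0.000842 estimated). The lysosomal channel gene Mcoln1 rose from 4.68 ± 2.43 to 38.6 ± 9.08 TPM (log2 change 2.88, adjusted p = 0.00455), the sialidase gene Neu1 from 4.63 ± 0.533 to 29.2 ± 3.74 (2.42, adjusted p = 9.25e-06) and the proton pump gene Atp6v0d1 from 12.5 ± 1.29 to 57.4 ± 3.54 (2.12, adjusted p = 4.75e-06). Of 15 mitochondrially encoded genes, 12 rose (12 adjusted over the list alone; adjusted p = 5.72e-11, and 0.0462 estimated), including COX2 from 9373 ± 153 to 15097 ± 600 TPM, against 6 with quantile normalization. Of 15 HDAC-inhibitor response markers, 10 rose and 4 fell (10 and 4 adjusted over the list alone; adjusted p = 6.45e-06, and 0.00532 estimated), with 2 rather than 4 lower under each of the 4 other scalings. Mt2 rose from 1308 ± 62.9 to 8660 ± 343 TPM, and cyclin D1 (Ccnd1) fell from 138 ± 6.2 to 73.8 ± 6.29.

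Of 7 BET-inhibitor response markers, 4 rose (4 adjusted over the list alone; adjusted p = 0.00901), and the list had adjusted p = 0.0639 with an estimated correlation. Hexim1 rose from 11.4 ± 1.98 to 44.3 ± 2.1 TPM (log2 change 1.88, adjusted p = 6.12e-06) and the linker histone gene H1f2 from 19.5 ± 1.32 to 82.8 ± 8.29. Of 10 genes of the BET family and P-TEFb, 3 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.0863), a list that passed with median-of-ratios scaling (0.0463), quantile normalization (0.0283, with 5 higher members) and multiplication by gene length (0.0445). Brd2 rose from 645 ± 13.7 to 2322 ± 158 TPM (1.84, adjusted p = 9.43e-10), while Brd3 (32.1 ± 7.48 TPM, adjusted p = 0.641) did not pass. Larp7, a P-TEFb regulator, fell from 224 ± 10.2 to 112 ± 3.44 TPM. Of 21 AP-1 genes, 11 rose and 3 fell (11 and 4 adjusted over the list alone; adjusted p = 0.000948), and the list had adjusted p = 0.0779 with an estimated correlation. Atf3 rose from 8.29 ± 1.84 to 40 ± 5.85 TPM and Fosl1 fell from 31.2 ± 4.47 to 3.26 ± 1.47. Of 85 cytosolic ribosomal protein genes, 52 fell and 9 rose (52 and 9 adjusted over the list alone; adjusted p = 6.24e-08), with adjusted p = 0.228 with an estimated correlation, and 41 and 15 over protein-coding nuclear genes alone. Rpl35 fell from 2237 ± 50.5 to 1370 ± 43.2 TPM and Rplp0 rose from 992 ± 15.9 to 1304 ± 1.95.

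The other lists did not pass with JQ1, although many held genes that changed in both directions. JQ1 changed 33.9% of all genes tested (1657 higher and 2690 lower of 12836), so called members are common in any list. Counts near these shares say nothing particular about a list. Of 49 histone genes, 12 rose and 10 fell (12 and 10 adjusted over the list alone; median −0.26, mean −0.11, test up, adjusted p = 0.557), with H2ac24 down from 3014 ± 80 to 506 TPM. Of 25 matrix genes, 11 rose and 9 fell (11 and 9; median 0.20, mean −0.06, test up, 0.384), with the protease inhibitor gene Timp2 up from 124 ± 6.08 to 490 ± 31.3 TPM and Col3a1 down from 19.2 ± 0.232 to 3.3 ± 0.598. Of 20 stress response genes, 7 rose and 4 fell (7 and 4; 0.224), with Ddit3, the stress factor CHOP, up from 24.4 ± 3.15 to 188 ± 24.8 TPM. Of 19 mesenchymal and contractile genes, 5 rose and 6 fell (5 and 8; median −0.06, mean 0.01, test up, 0.677), but the counts were 6 and 5 and the median 0.05 with median-of-ratios scaling. Their matricellular member Ccn1 rose from 41.9 ± 2.78 to 231 ± 9.48 TPM, and smooth muscle actin (Acta2) fell from 51.7 ± 7 to 22.3 ± 3.67. Of 8 antigen presentation genes, 4 rose and 3 fell (4 and 3; median 0.38, mean −0.20, test up, 0.428), with H2-D1 up to 54.9 ± 3.22 TPM. Of 13 NF-kB genes, 2 rose and 6 fell (2 and 6; 0.334), with Nfkbia up from 106 ± 5.53 to 356 ± 9.37 TPM and Vcam1 down from 8.55 ± 0.711 to 0.993 ± 0.506. Of 13 interferon-stimulated genes, 5 fell (6; 0.35), among them Isg15 from 22.6 ± 5.82 to 5.83 ± 2.83 TPM.

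Of 16 p53 targets, 4 rose and 1 fell with JQ1 (4 and 1 adjusted over the list alone; median −0.15, mean 0.18, test up, adjusted p = 0.548), with Gadd45a up from 10.5 ± 2.73 to 46.9 ± 4.68 TPM. Of 10 HDAC family genes, Hdac5 rose from 66.5 ± 6.71 to 116 ± 9.51 TPM and Hdac2 fell from 82.7 ± 17.5 to 40.5 ± 1.48 (1 and 1; 0.711), while Hdac1 (59.4 ± 3.49, adjusted p = 0.285) and Hdac3 (5.39 ± 0.361, adjusted p = 0.307) did not pass. Of 6 neuronal genes, Gap43 fell to 2.82 ± 1.45 TPM (1; median 0.36, mean −0.20, test up, 0.711). Of 12 BCL2 family genes, 2 rose and 2 fell (3 and 2; median −0.20, mean −0.21, test up, 0.744), with the proapoptotic Bcl2l11 up from 8.33 ± 0.987 to 18.8 ± 0.925 TPM. The counts were 2 higher and 3 lower of 22 cholesterol genes (2 and 3; median 0.05, mean −0.00, test up, 0.701), but 3 and 2 with median-of-ratios scaling and 4 and 1 with quantile normalization. They were 3 and 3 of 12 cilia and tubulin genes (3 and 3; 0.384), and 5 and 2 with quantile normalization. Of 15 glycolysis genes, 1 rose and 5 fell (1 and 6; 0.384), with lactate dehydrogenase (Ldha) down from 165 ± 10 to 73.4 ± 10.8 TPM, but the counts were 4 and 3 with median-of-ratios scaling, quantile normalization or protein-coding nuclear genes alone and 3 and 3 after multiplication by gene length. The list median of −0.17 became 0.04 with quantile normalization. Of 9 angiogenic genes, 1 rose and 4 fell (1 and 4; 0.249), with Vegfd down from 8.3 ± 0.53 to 0.657 ± 0.349 TPM. Cd34 fell to 52.5 ± 0.552 TPM, with 2 of 5 blood endothelial genes lower (2; 0.35), and Pdpn to 46.9 ± 1.89, with 2 of 2 lymphatic genes lower (2; 0.107). Of other cell types' markers, 2 of 5 fibroblast genes (2; 0.35) and 1 of 3 leukocyte genes (1; 0.711) fell, Krt19 rose to 34.2 ± 5.34 TPM (1), and limma made 0 calls for the 1 tested pericyte marker (0 at an unadjusted p under 0.05 and 0 adjusted over the list alone).

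With JQ1, 1657 genes were higher and 2690 lower, 33.9% of those tested, and 707 and 1235 changed at least 2-fold. Lower genes were 61.9% of the calls, 52.1% with median-of-ratios scaling and 51.5% with quantile normalization. Median-of-ratios scaling moved the median change of all genes by 0.107 and a restriction to protein-coding nuclear genes by 0.108, so JQ1 changes of this size turn on the scaling.

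**Figure D3:**
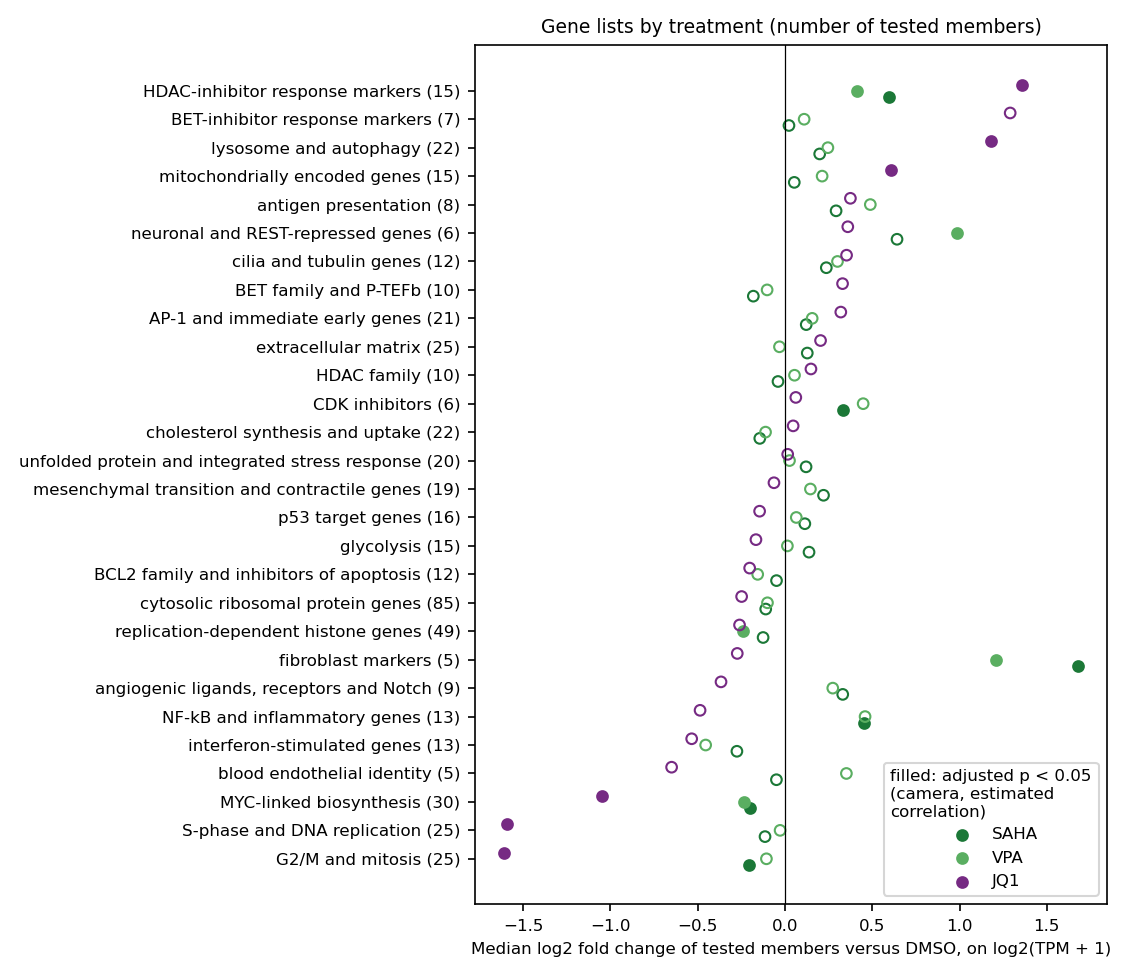
Median log2 change against DMSO (horizontal axis) of the tested members of each gene list with at least 5 of them, for SAHA (dark green), VPA (light green) and JQ1 (purple); filled points have a camera adjusted p under 0.05 with an estimated correlation. The JQ1 medians of the S-phase (−1.59), G2/M (−1.61) and MYC-linked (−1.05) lists lie farthest to the left.

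Set directly against the HDAC inhibitors, JQ1 gave lower levels of Il1rl1, Grem1, Fst and Gap43. Il1rl1 stood at 275 ± 35.9 TPM with SAHA and 175 ± 4.46 with VPA against 3.88 ± 4.25 with JQ1 (log2 differences 6.16 and 5.52, adjusted p = 1.19e-06 and 2.75e-06). Grem1 stood at 258 ± 10.6 and 197 ± 5.5 against 6.23 ± 1.41 TPM (5.18 and 4.80), and follistatin (Fst), an activin antagonist, at 105 ± 10.4 and 125 ± 19.4 against 2.35 ± 1.92 (5.14 and 5.38). Gap43, which rose with both HDAC inhibitors and fell with JQ1, differed by 4.88 and 5.08. In the other direction, H2bc4 stood at 7.47 ± 6.08 TPM with SAHA and 8.77 ± 0.91 with VPA against 132 ± 10.1 with JQ1 (−4.32 and −3.77), and Klf2 at 11.2 ± 1.87 with SAHA against 149 ± 2.64 (−3.64).

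In all, 2737 genes were higher and 1533 lower with SAHA than with JQ1 (4270), and 2945 and 1319 with VPA than with JQ1 (4264). In each of these comparisons 9 of the 10 genes named for size kept their call whichever library was left out. The exceptions were Snord118 with VPA (4.04 ± 7 against 52.6 ± 18.5 TPM), whose call ended without VPA or JQ1 replicate 2 or 3 (up to 0.0891, without VPA replicate 2), and Snord83b with SAHA (13.1 ± 22.6 against 108 ± 39.1), whose call ended without SAHA replicate 1 or 2, VPA replicate 1 or 3 or any JQ1 replicate (up to 0.132, without SAHA replicate 1).

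Against DMSO, SAHA and JQ1 shared 173 higher and 160 lower genes, where independent lists would share 51.1 and 56.6, and 138 genes changed in opposite directions (100 higher with SAHA and lower with JQ1, 38 the reverse, against 83 and 34.9). VPA and JQ1 shared 175 and 104 genes (independent lists 48.9 and 35.4), and 93 changed in opposite directions (69 and 24, against 79.4 and 21.8). Simulated unchanged groups shared 0 in both pairs, which again sets no bound on what the shared controls add. The correlations across genes were 0.294 and 0.321 (simulated 0.499) and the covariances 0.134 and 0.145 (simulated 0.0826), differences of 0.0514 and 0.0627. Part of these excesses may come from the shared controls. The numbers for independent lists also treat genes of every expression level as equally likely to be called. For the 208 genes raised by both HDAC inhibitors, random lists matched on expression held 34.3% of genes lower with JQ1. Among all genes tested, 2690 of 12836 were lower. The independent numbers are therefore no firm baseline for genes shared or changed in opposite directions. The 333 genes shared by SAHA and JQ1 in direction became 184, 186 and 190 without DMSO replicates 1, 2 and 3, and 205, 189 and 197 without SAHA replicates 1, 2 and 3. The 279 shared by VPA and JQ1 became 148, 162 and 156 without DMSO replicates 1, 2 and 3, and 161, 155 and 166 without VPA replicates 1, 2 and 3.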

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

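Under the alternatives tried, no result changed direction past its threshold. Of 360 values of 15 counts, 286 stayed within 1.5 times the reported count. Of 312 gene results, 210 kept their direction and side of the threshold under every alternative run, and of 7137 values 6452 did so, 678 were no longer past it and 7 newly were. Of 90 list results, 64 did so throughout, and of 2154 values 2099 did so, 40 were no longer past the threshold and 15 newly were.

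In a fit of the 2 compared groups alone, which has fewer samples, SAHA had 214 higher and 155 lower genes, VPA 173 and 70, and SAHA and VPA differed in 19, of which 9 were among the 58 reported. The genes shared in direction were then 124 for SAHA and VPA, 177 for SAHA and JQ1 and 104 for VPA and JQ1. With a log2 change of at least 1, a stricter bound by construction, the counts were 133 and 54 for SAHA, 141 and 35 for VPA, 707 and 1235 for JQ1, 14 for SAHA against VPA, 2011 for VPA against JQ1 and 1951 for SAHA against JQ1, and the shared genes 77, 59 and 55 in the order above. Median-of-ratios scaling gave 264 lower genes for VPA and 88 that differed between SAHA and VPA; the cause was not tested. With an estimated correlation, 6 rather than 12 lists passed for SAHA and 5 rather than 13 for VPA.

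Leaving out 1 of the 12 libraries at a time, which leaves fewer samples, gave 218 (without SAHA replicate 2) to 373 higher and 126 (without DMSO replicate 2) to 264 lower genes for SAHA. The ranges were 209 (without VPA replicate 1) to 349 and 73 (without DMSO replicate 1) to 159 for VPA, and 15 (without SAHA replicate 3) to 61 for SAHA against VPA. Shared genes ranged from 163 (without DMSO replicate 3) to 272 for SAHA and VPA, 184 (without DMSO replicate 1) to 305 for SAHA and JQ1, and 148 (without DMSO replicate 1) to 260 for VPA and JQ1. The JQ1 counts stayed within 1.5 times, at 1297 to 1667 higher and 2321 to 2695 lower.

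No pairing of samples by replicate number was seen: residual correlations of the 18 same-number pairs lay between −0.0449 and 0.0789, inside the bound of 0.1. That bound was set by choice, and a correlation over all genes can miss a batch that affects few of them. With a replicate block 24 genes differed between SAHA and VPA, 23 of them among those 58, and the G2/M list of VPA no longer passed (0.0604); the cause was not tested. Sequencing depth is unknown, so what it limits cannot be given.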

Other observations

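The 12 gene families of the next paragraph, the tests of the nuclear RNAs, of the mitochondrial copies and scaling, of the histones, of opposite directions and of JQ1 calls of at least 2-fold were chosen only after the results were seen. The tests of the excess among all JQ1 calls and of other splits were not. After a first run the bound for the JQ1 excess was made stricter, by asking for more than the spread over left-out libraries, which left the value after multiplication by gene length undecided. For calls of at least 2-fold, the spread was later taken from their own share and the value after multiplication by gene length was added. That value passes the bound with this spread but not with the earlier one, so it is left undecided. For S phase, class sums later replaced a count of the histone genes that rose, which had left it undecided, and the sums do not decide it either. The test of opposite directions was set to undecided because shared controls push toward equal directions.

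Among 12 families tested against each drug (36 tests, adjusted together, estimated correlation), 5 passed with JQ1. The adjustment does not cover the choice of families after the results were seen. Of 78 mitochondrial ribosomal protein genes, 48 fell and 1 rose (adjusted p = 0.00929; 41 and 2 with median-of-ratios scaling), such as Mrpl12 from 135 ± 4.03 to 70 ± 3.25 TPM. Of 37 proteasome genes, 27 fell and 1 rose (adjusted p = 0.00788; 22 and 3 with that scaling). Of 46 translation initiation factors, 25 fell and 1 rose (adjusted p = 0.0427; 22 and 6), with Eif5a from 864 ± 18.5 to 349 ± 9.06 TPM (log2 change −1.31), and of 17 tRNA synthetases 11 fell and 1 rose (adjusted p = 0.0427; 9 and 1). Of 16 vacuolar ATPase genes, 12 rose (adjusted p = 0.00929; 12 with that scaling), including Atp6v0c from 282 ± 25.6 to 571 ± 35.2 TPM. In VPA, 4 of 38 complex I genes rose (adjusted p = 0.0278; 1 with that scaling). The 15 snoRNA host genes had a median of −0.38 there (adjusted p = 0.0365), although limma called 0 of them (8 at an unadjusted p under 0.05; 2 lower with that scaling). In SAHA, 4 of 31 box H/ACA snoRNAs fell (adjusted p = 0.0427), with uncertain levels since division by length inflates short genes. How much snoRNA the 3′-end libraries capture is not known either. The ferritin light chain Ftl1, chosen after its values were seen, rose with JQ1 from 2336 ± 42.2 to 13532 ± 291 TPM, a level that pseudogene copies make uncertain.

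For each comparison, a fit of its 6 libraries alone was repeated over the 10 splits into 3 and 3, to ask about the grouping of libraries by chance. The number of splits with as many genes as the real one was 1, the real split itself, in each of the 6 comparisons. The real count and the highest of the others were 369 and 12 for SAHA against DMSO, 243 and 11 for VPA, 3945 and 14 for JQ1, 19 and 12 for SAHA against VPA, 3814 and 17 for VPA against JQ1, and 3813 and 5 for SAHA against JQ1. With 10 splits the share cannot fall under 0.05.

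JQ1 calls were lower in 61.9% of cases, and in 63.6% of those of at least 2-fold. The share ranged from 61.8 to 64.9% over left-out libraries (SD 1.11) and was 52.1% with median-of-ratios scaling, 53.3% for protein-coding nuclear genes and 55.3% after multiplication by gene length, and at 2-fold 52.6%, 54.3% and 56% in the same order (SD 0.549 over left-out libraries). The 56% lies narrowly above the bound of 55%, by more than that SD. That SD belongs to the share without multiplication by gene length and was chosen after an earlier spread had left the value undecided. The 56% therefore does not decide whether the length division is the whole cause of the excess at 2-fold. The other values lie between the 50% that each technical cause would give and that bound with its spread, so much of the excess may come from scaling, composition or, among all calls, the length division, and what part does stays open. No biological explanation was tested apart from the drug itself.

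JQ1 raised Malat1 and mitochondrially encoded RNAs. The summed share of mitochondrial genes and 3 nuclear copies was 1.34 times that of DMSO (16.4 ± 0.548 against 12.2 ± 0.15%), which argues against reads moved between them. The mitochondrial median (0.61 as reported) was 0.733 over 15 genes with median-of-ratios scaling, which moves JQ1 changes upward and so is a weak test. With quantile normalization it was 0.31, with 6 rather than 12 genes higher and a camera adjusted p of 0.000438 at the preset correlation. These 6 calls, with 0 lower, argue against scaling as the whole cause for those genes, but part of the rise may come from it. The p of 0.000438 is not weighed here. With an estimated correlation of 0.255, the camera adjusted p of the values as reported went from 5.72e-11 to 0.0462. A general rise of nuclear-retained RNA stays open: the other 4 had a median of 0.72 (0.715), with Neat1 higher (8.37 ± 0.804 to 58.3 ± 3.78 TPM), Pvt1 lower (21.5 ± 3.01 to 11.2 ± 1.89) and Tug1 and Airn not past the threshold.

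Histone genes moved both ways with JQ1. Summed within classes, 5 of 5 differed at least 1.5-fold from DMSO without overlap of libraries (chance gives 10%): H1 121 against 215 TPM, H2A 666 against 3329, H2B 150 against 28, H3 76.1 against 16.1 and H4 170 against 50.5. That argues against reads shared between near-identical histone genes of a class as the whole cause. The sums of 3 of the 5 classes, H2B, H3 and H4, were higher by that measure, where fewer cells in S phase alone was predicted to lower all of them. Single genes carried much of the H2B, H4 and H2A changes. From DMSO to JQ1, H2bc4 went from 9.55 to 132 TPM, H4c9 from 11.5 to 114.5 and H2ac24 from 3014 to 506. How much S-phase histone RNA these 3′-end libraries capture is not known here, so the class sums may not follow total histone RNA. The sums therefore do not decide whether fewer cells in S phase were the cause, for the lower sums or the higher ones.

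The hypothesis that the same genes move in opposite directions was tested on the 208 genes raised by both HDAC inhibitors. JQ1 lowered 52 of them, where random lists matched on expression gave a mean of 71.2 (percentile 0.09), and raised 103 (random mean 32.9). Of the 92 genes lowered by both, JQ1 lowered 61 (36.8) and raised 12 (15.7). Shared controls push these counts toward equal directions, so the hypothesis stays open.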
